A study of Homo sapiens with 8 samples.

How the data were processed

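RNA was measured in 8 libraries of HL-60 cells in 4 groups of 2: DMSO, decitabine, RG3039 and the combination. Per the labels, wells were seeded in duplicate, decitabine (100 nM) was added daily from day 0 to day 2, RG3039 (2 µM) once on day 0, and RNA was taken at 72 h. Libraries of polyadenylated RNA were made with the QuantSeq 3′ mRNA-Seq FWD kit and sequenced single-end on an Illumina HiSeq. Such libraries count 1 tag near the 3′ end of each transcript. The strand setting of the counting is not given in the sources used here, and reads shared between near-identical genes (defensins, α-tubulins, histones, MT1 genes, NCF1) make their levels uncertain.

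The deposited values are a signal per gene: normalised read counts for 60240 genes with versioned Ensembl identifiers. Per the submitters' processing notes the tools were Salmon 1.2.1, STAR, featureCounts, DESeq2 and limma with hg38, without saying which step made the values. Tests on the values gave the following. All 8 libraries had the same median ratio to the geometric mean per gene. In genes with 1 annotated transcript, 97.5% to 98.1% of low values (up to 20.5 reads) were whole multiples of a step per library within a tolerance of 0.02, against 32.4% to 43.1% in genes with 5 or more transcripts and 74.4% to 80.8% over all genes. Whole reads were therefore recovered for part of the genes only, and no count test was run. The step, which is the value of 1 read, lay between 0.702 and 1.51, and the total divided by it gave the estimated depth. Totals of normalised values were 27900000 to 32300000 per library. Of the 60240 identifiers, 58064 were found in GENCODE 29, from which coordinates on GRCh38 (hg38) and transcript numbers were taken, 59997 in the table of gene names, and 31387 were above 0 in at least 1 library.

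Genes with a mean value of at least 10 over the 8 libraries were tested (17534). Values were taken as log2(value + 1), and 1 linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with the mean-variance trend), so the 4 groups shared 1 estimate of the spread with 4 residual degrees of freedom and 5.51 prior ones. In all, 6 contrasts were tested: each treatment against DMSO, the combination against each single drug, and the interaction, which is (combination - decitabine) - (RG3039 - DMSO). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. The median standard error of a log2 fold change was 0.322, and 0.456 for the interaction. In simulated data of the same size 26.9% to 43.3% of 2-fold changes and 87.9% to 97.0% of 8-fold changes were recovered in the pairwise contrasts.

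Before the data were examined, 22 gene lists were written (1055 symbols, all matched, 911 tested) and tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. camera's own version with an estimated correlation also takes the 4 residual degrees of freedom; no list passed in it in any comparison, and the estimated correlation was therefore also held fixed, which was chosen after seeing the data. The genes to be named were fixed by a rule before the data were examined. They are, among called genes with a mean value of at least 20 whose groups do not overlap, the 8 with the largest positive and the 8 with the largest negative log2 fold change against DMSO (5 and 5 in the other contrasts), the 4 members of each list with the smallest p in each contrast, and DNMT1, DNMT3A, DNMT3B, UHRF1 and DCPS. From these, the text leads with genes that kept their call without each of the 8 libraries. Some genes within the rule are not reported here. MYC and the metallothionein genes other than MT1M lie outside it. Where a gene is at 0 in a whole group, its values are given and no fold change, since a value listed at 0 need not mean that no read was present.

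Overlaps between contrasts that share the DMSO libraries were set against the number expected of independent lists. The correlations and covariances of fold changes were set against 20 simulations of unchanged groups with shared controls. Both were also computed with a DMSO library of its own for each comparison, which was chosen after seeing the data. Alternatives tried were TMM and quantile scaling, other pseudocounts, other filters on low values, eBayes with robust estimates or without the trend, only the groups compared, the replicate number as a block, a fold threshold, and leaving out each library. Count models on recovered reads were planned and not run, since reads were recovered for part of the genes only. X-inactivation and Y-linked genes were left out of the genes to be named. Data were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.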

Results

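The transcriptome of HL-60, a human promyelocytic leukaemia cell line, was measured by 3′ RNA sequencing at 72 h in 4 groups of 2 libraries each. Cells received the solvent DMSO, decitabine, RG3039, or decitabine and RG3039 together (the combination). Decitabine is a deoxycytidine analogue that is built into DNA and inhibits DNA methyltransferases. It was added 3 times, daily from day 0 to day 2, at a dose of 100 nM. RG3039 inhibits DcpS, the scavenger enzyme that breaks down the cap left after mRNA decay, and was added once at the start, at 2 µM. The design compares expression between the 4 treatments. Because both single drugs are present, it also allows a test of whether the response to both departs from the sum of the single responses. The estimated depth was 40100000 and 21400000 reads for the DMSO libraries, 20700000 and 28600000 for decitabine, 22000000 and 37100000 for RG3039 and 33500000 and 40900000 for the combination. Between 22205 and 25549 genes were listed above 0 per library, and 17534 genes with a mean value of at least 10 were tested.

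The treatments took separate places on the first 2 principal components. On the first principal component, with 34.5% of the variance, the DMSO libraries lay at -79.5 and -84.6 and the combination at 87.7 and 69.4. Both single treatments lay between them, decitabine at -8.45 and -3.41 and RG3039 at 4.22 and 14.7. The second component, with 19.8%, set decitabine (60.5 and 59.6) apart from RG3039 (-70.5 and -51.8). Correlations between the 2 libraries of a group, taken across genes, ran from 0.952 to 0.957. Between libraries of different groups they ran from 0.890 (DMSO replicate 2 and combination replicate 1) to 0.9535 (RG3039 replicate 2 and combination replicate 2), so the ranges overlapped. Mitochondrially encoded transcripts made up 11.01% and 10.4% of the signal in DMSO, 12.5% and 11.04% with decitabine, 12.4% and 11.4% with RG3039 and 11.98% and 12.6% with the combination. Ribosomal protein genes made up 17.4% to 18.1% in the 4 libraries given RG3039 and 18.75% to 20.1% in the other 4.

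**Figure D1:**
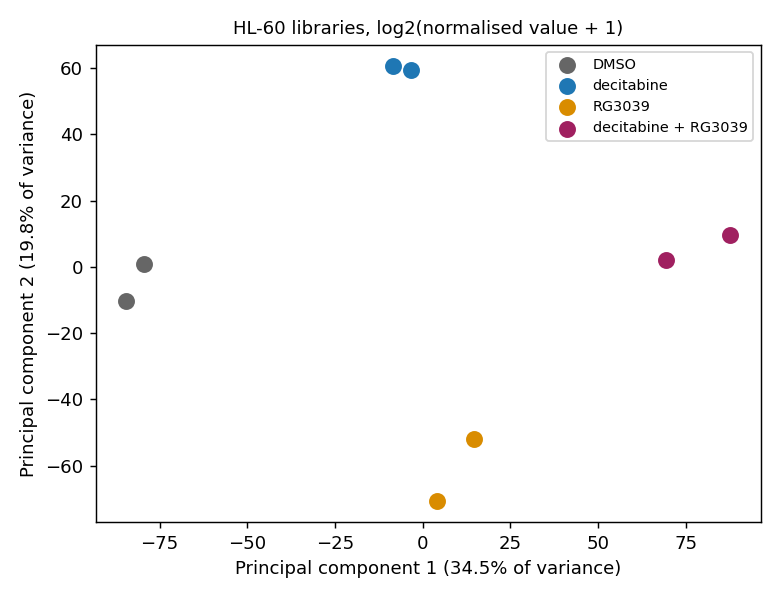
The 8 libraries on the first 2 principal components of log2(normalised value + 1), in arbitrary units, with 1 point per library and a colour per treatment. The DMSO libraries lie at -79.5 and -84.6 on component 1 and the combination libraries at 87.7 and 69.4, with the single treatments between them and apart on component 2.

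Numbers in parentheses after a gene are log2 fold changes ± the standard error from the model, on the scale of log2(normalised value + 1), which understates the change of low genes. The error rests on 2 libraries per group. A gene is called when its adjusted p from limma over the 17534 genes is under 0.05. For gene lists fixed in advance, medians are of log2 fold changes and p-values come from camera at its preset correlation. In camera's own version with an estimated correlation, which also rests on 4 degrees of freedom, no list passed in any comparison. With that correlation held fixed, a test added after the data were seen, 7 of 12 list calls held for decitabine, 4 of 7 for RG3039 and 11 of 13 for the combination against DMSO. It left 5 of 10 for the combination against decitabine, 11 of 12 for the combination against RG3039 and 0 of 6 for the interaction.

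DNMT1, the maintenance DNA methyltransferase and a target of decitabine, had normalised values of 12682 ± 1603 in DMSO, 11243 ± 2568 with decitabine, 8036 ± 2101 with RG3039 and 5404 ± 794 with the combination (mean ± SD, n = 2). It fell with the combination against DMSO (-1.23 ± 0.22, adjusted p = 0.00370) and against decitabine alone (-1.05 ± 0.22, adjusted p = 0.0226). The latter call was lost at adjusted p = 0.142 without decitabine replicate 1, 0.164 without combination replicate 1 and 0.0780 without combination replicate 2. UHRF1, which guides DNMT1 to newly replicated DNA, fell with the combination (-0.72 ± 0.17, adjusted p = 0.0146), a call lost at adjusted p = 0.0809 without DMSO replicate 2, 0.0808 without combination replicate 1 and 0.0705 without combination replicate 2. With decitabine alone the changes were -0.19 ± 0.22 for DNMT1 and -0.23 ± 0.17 for UHRF1 (adjusted p = 0.704 and 0.527). With RG3039 alone they were -0.68 ± 0.22 and -0.29 ± 0.17 (adjusted p = 0.0988 and 0.365). The de novo methyltransferase genes were not called in any comparison. DNMT3A gave 0.18 ± 0.25, -0.21 ± 0.25 and 0.06 ± 0.25 with decitabine, RG3039 and the combination against DMSO, and DNMT3B gave 0.08 ± 0.37, -0.79 ± 0.37 and 0.01 ± 0.37. DCPS, which encodes the target of RG3039, had values of 808 ± 215 in DMSO, 982 ± 167 with decitabine, 813 ± 217 with RG3039 and 479.5 ± 89.4 with the combination. Its change with RG3039 alone was 0.01 ± 0.27 (adjusted p = 0.992). DCPS was called only in the combination against decitabine, where it was lower (-1.04 ± 0.27, adjusted p = 0.0477). That call was lost at adjusted p = 0.227 without decitabine replicate 1, 0.0917 without decitabine replicate 2, 0.0504 without RG3039 replicate 1, 0.114 without combination replicate 1 and 0.236 without combination replicate 2.

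Against DMSO, decitabine raised genes that were low or near 0 in DMSO. The collagen gene COL14A1 (ENSG00000187955.12, chromosome 8, 120059780 to 120372036 on GRCh38) went from 0.426 and 0 in the DMSO libraries to 638 and 642 (9.07 ± 0.76, adjusted p = 0.000544). The transketolase-like gene TKTL1 (ENSG00000007350.17, chromosome X, 154295671 to 154330350) went from 1.51 and 0 to 380.2 and 423 (7.99 ± 0.73, adjusted p = 0.000747). The homeobox gene OTP (ENSG00000171540.7, chromosome 5, 77628712 to 77639688) went from 0.637 and 0 to 294 and 179 (7.49 ± 0.72, adjusted p = 0.000933). PNMA5, of the paraneoplastic antigen family (ENSG00000198883.12, chromosome X, 152988824 to 152994127), rose from 19.7 and 39.2 to 7735 and 10197 (8.27 ± 0.32, adjusted p = 6.27e-06). The α-tubulin gene TUBA3D was listed at 0 in both DMSO libraries and at 127 and 106 with decitabine (adjusted p = 0.00173). Near-identical tubulin copies make its level uncertain.

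In all, 376 genes were called with decitabine, 305 higher and 71 lower, and 296 of them changed at least 2-fold. The number called was 225 with no filter on low values, 210 without the mean-variance trend and 105 with only the groups compared. The tested cancer-testis and germline genes, a class silenced by DNA methylation in most somatic cells, rose as a set, which the filter on the mean favours. Of 37 tested members, 10 were called higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 1.25, at camera adjusted p = 6.79e-11 (adjusted p = 0.113 with an estimated correlation). Leaving out the 4 members listed at 0 in a whole group of the comparison gave a median of 0.99. Besides TKTL1 and TUBA3D they included MAGEB2 (3.35 ± 0.32), a MAGE family antigen, and MAEL (4.08 ± 0.42), a factor of the germline piRNA pathway, at adjusted p = 0.000897 and 0.00157. Myeloid granule genes rose as well. Of 29 primary granule and promyelocyte genes, 8 were called higher and 0 lower (15 and 2 adjusted over the list alone). Their median was 0.46, at camera adjusted p = 9.68e-08 (adjusted p = 0.190 with an estimated correlation). They included PRG2 (1.67 ± 0.14) and CLC (1.82 ± 0.20), which encode the eosinophil major basic protein and the Charcot-Leyden crystal protein, at adjusted p = 0.000544 and 0.00192. Of 60 monocyte and granulocyte maturation markers, 7 were called higher and 1 lower (18 and 2 adjusted over the list alone). Their median was 0.41, at camera adjusted p = 8.08e-07 (adjusted p = 0.147 with an estimated correlation). MMP9, the gelatinase of neutrophil granules (ENSG00000100985.7, chromosome 20, 46008908 to 46016561), led them at 3.17 ± 0.33 (adjusted p = 0.00153).

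GBP2, an interferon-inducible GTPase (2.47 ± 0.26), rose with decitabine at adjusted p = 0.00173. Its list did not pass, nor did antigen presentation genes. Of 49 interferon-stimulated genes, 2 were called higher and 0 lower (6 and 1 adjusted over the list alone). Their median was 0.06 (camera adjusted p = 0.165). Of 27 antigen presentation genes, 1 was called higher and 1 lower (2 and 1 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 0.213). The stem cell transcription factor gene GATA2 rose (2.35 ± 0.17, adjusted p = 0.000235). Of 25 erythroid and megakaryocyte markers, which include GATA2, 2 were called higher and 0 lower (2 and 0 adjusted over the list alone). Their median was 0.85, at camera adjusted p = 0.000258 (adjusted p = 0.398 with an estimated correlation). This call was lost at adjusted p = 0.403 without DMSO replicate 2. Of 19 markers of lymphoid, stromal and epithelial cells, types that a pure HL-60 culture does not hold, 1 was called higher and 0 lower (2 and 0 adjusted over the list alone). Their median was 1.11, at camera adjusted p = 0.000134 (adjusted p = 0.120 with an estimated correlation).

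Genes of MYC and ribosome biogenesis fell as a set with decitabine. Of 41 tested members, 0 were called higher and 3 lower (0 and 17 adjusted over the list alone). Their median was -0.45, at camera adjusted p = 3.29e-14 (adjusted p = 0.157 with an estimated correlation). Of 75 spliceosome genes, 0 were called higher and 1 lower (0 and 0 adjusted over the list alone). Their median was -0.26, at camera adjusted p = 1.45e-08 (adjusted p = 0.160 with an estimated correlation). Of 72 mRNA decapping and decay genes, 1 was called higher and 0 lower (1 and 0 adjusted over the list alone). Their median was -0.24, at camera adjusted p = 0.000143 (adjusted p = 0.272 with an estimated correlation). A further 4 lists passed and lost the call without some library. The m6A genes had a median of -0.24, at camera adjusted p = 0.00952 (adjusted p = 0.203 with an estimated correlation), lost at adjusted p = 0.0531 without DMSO replicate 2. Cholesterol biosynthesis genes had a median of -0.24, at camera adjusted p = 0.00952 (adjusted p = 0.236 with an estimated correlation), lost at adjusted p = 0.170 without DMSO replicate 1 and 0.0551 without decitabine replicate 1. Lysosome genes had a median of 0.16, at camera adjusted p = 0.00952 (adjusted p = 0.272 with an estimated correlation), lost at adjusted p = 0.229 without decitabine replicate 2. Histone genes had a median of 0.19, at camera adjusted p = 0.0358 (adjusted p = 0.259 with an estimated correlation), lost at adjusted p = 0.216 without DMSO replicate 1, 0.0728 without decitabine replicate 1 and 0.0625 without decitabine replicate 2. With the estimated correlation held fixed, the list calls for mRNA decapping and decay, cholesterol biosynthesis, lysosome, histone and erythroid and megakaryocyte did not hold. Other lists did not pass, among them p53 targets (median 0.07, camera adjusted p = 0.213) and imprinted genes (median 0.38, camera adjusted p = 0.135). Median, mean and test direction differed in sign for apoptosis regulators (-0.06, 0.04 and down) and DNA methylation machinery and decitabine metabolism genes (-0.07, 0.01 and down). Among single genes CCR2, a chemokine receptor (ENSG00000121807.5, chromosome 3, 46353734 to 46360928), fell by 1.69 ± 0.23 on the log2 scale (adjusted p = 0.00700), a call lost at adjusted p = 0.0513 without DMSO replicate 2, 0.0622 without decitabine replicate 1 and 0.0501 without decitabine replicate 2. Of 47 called genes within the naming rule, 13 kept the call without each of the 8 libraries. Every called gene named for this comparison except CCR2 is among them. The number of called genes was 145 without DMSO replicate 2, 86 without decitabine replicate 1, 79 without decitabine replicate 2, 162 without combination replicate 1 and 156 without combination replicate 2, where a lone library is assumed to vary like the other groups.

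With RG3039 alone, IGFBP7, an insulin-like growth factor binding protein gene (ENSG00000163453.11, chromosome 4, 57030773 to 57110385 on GRCh38), fell from 2426 ± 513 in DMSO to 17.4 ± 2.84 (mean ± SD, n = 2). Its change was -7.04 ± 0.34 (adjusted p = 5.28e-05). TFEC, a transcription factor gene of the MiT family (ENSG00000105967.16, chromosome 7, 115935148 to 116159896), fell from 1112 ± 360.4 to 11.8 ± 9.88 (-6.66 ± 0.55, adjusted p = 0.000406). PPP1R1B, which encodes the phosphatase inhibitor DARPP-32 (ENSG00000131771.14, chromosome 17, 39626740 to 39636626), rose from 4.17 ± 2.68 to 222 ± 16.3 (5.53 ± 0.40, adjusted p = 0.000281). The keratin gene KRT86 (5.42 ± 0.84), the metallothionein gene MT1M (5.24 ± 0.62) and the small heat shock protein gene HSPB6 (5.23 ± 0.74) rose as well, at adjusted p of 0.00470 or less. KRT86 and MT1M have close paralogs, so their levels are uncertain. GP1BB, a platelet glycoprotein gene, was listed at 0 in both RG3039 libraries. It stood at 273 and 27.2 in DMSO, 639 and 533 with decitabine and 1013 and 665 with the combination.

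In all, 1424 genes were called with RG3039, 794 higher and 630 lower, and 990 of them changed at least 2-fold. Without the mean-variance trend 718 were called, and with only the groups compared 481. Myeloid maturation markers rose. Of 60 tested markers, 25 were called higher and 3 lower (27 and 5 adjusted over the list alone). Their median was 0.61, at camera adjusted p = 1.01e-07 (adjusted p = 0.160 with an estimated correlation). They included MMP9 (3.59 ± 0.33), EGR1 (2.17 ± 0.23) and S100A9 (1.56 ± 0.16), at adjusted p of 0.000857 or less. EGR1 encodes a transcription factor of monocyte differentiation, and S100A9 a calcium-binding protein of mature phagocytes. Primary granule and promyelocyte genes went both ways. Of 29 tested members, 8 were called higher and 8 lower (11 and 11 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.862). The near-identical defensin genes DEFA1 (-1.49 ± 0.16) and DEFA3 (-1.85 ± 0.22), which share reads, and the cathepsin G gene CTSG (-1.74 ± 0.21) fell. The eosinophil ribonuclease gene RNASE3 rose (1.38 ± 0.18). These 4 genes had adjusted p of 0.00200 or less.

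Genes listed as p53 targets rose with RG3039. Of 36 tested members, 8 were called higher and 1 lower (15 and 1 adjusted over the list alone). Their median was 0.45, at camera adjusted p = 0.000215 (adjusted p = 0.160 with an estimated correlation). They included SAT1 (1.42 ± 0.17), BBC3 (1.39 ± 0.17) and NINJ1 (1.23 ± 0.17), at adjusted p of 0.00276 or less, which encode a polyamine acetyltransferase, the pro-apoptotic protein PUMA and a membrane rupture protein. Of 45 apoptosis regulators, 8 were called higher and 2 lower (8 and 4 adjusted over the list alone). Their median was -0.10 (camera adjusted p = 0.547). Among them BCL2A1 rose (1.49 ± 0.19) and BCL2, which encodes an inhibitor of apoptosis, fell (-0.90 ± 0.14), at adjusted p = 0.00187 and 0.00465. CDA, which encodes the cytidine deaminase that inactivates decitabine (ENSG00000158825.6, chromosome 1, 20588948 to 20618908), rose from 425 ± 65.0 to 2218 ± 192 (mean ± SD, n = 2; 2.39 ± 0.19, adjusted p = 0.000372). Of 32 DNA methylation machinery and decitabine metabolism genes, CDA included, 2 were called higher and 0 lower (2 and 0 adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.774).

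Of 53 lysosome genes, 8 were called higher and 1 lower (12 and 2 adjusted over the list alone). Their median was 0.23, at camera adjusted p = 0.0231 (adjusted p = 0.515 with an estimated correlation). GAA, the acid α-glucosidase gene (3.38 ± 0.38), and TFE3, a transcription factor gene of lysosome biogenesis (1.59 ± 0.24), rose at adjusted p = 0.00119 and 0.00388. Of 51 histone genes, 4 were called higher and 0 lower (6 and 2 adjusted over the list alone). Their median was 0.37, at camera adjusted p = 0.00365 (adjusted p = 0.300 with an estimated correlation). H2BC21 led them (2.56 ± 0.28, adjusted p = 0.00109). Of 42 integrated stress response genes, 7 were called higher and 2 lower (8 and 6 adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.214). Among them SLC7A11 (1.39 ± 0.18), ATF5 (1.00 ± 0.14) and TRIB3 (1.14 ± 0.17) rose at adjusted p of 0.00364 or less, and XBP1 fell (-1.22 ± 0.17, adjusted p = 0.00311). Genes of MYC and ribosome biogenesis fell as a set. Of 41 tested members, 0 were called higher and 4 lower (0 and 19 adjusted over the list alone). Their median was -0.43, at camera adjusted p = 3.12e-09 (adjusted p = 0.300 with an estimated correlation). MYC itself, which is amplified in HL-60, lies outside the naming rule and was chosen after its values were seen. It gave -1.07 ± 0.29 (adjusted p = 0.0565) and was not called. The adjusted p was 0.120 without DMSO replicate 1, 0.210 without DMSO replicate 2, 0.0394 without decitabine replicate 1, 0.0393 without decitabine replicate 2, 0.0574 without RG3039 replicate 1, 0.3005 without RG3039 replicate 2, 0.0813 without combination replicate 1 and 0.0830 without combination replicate 2. Mitosis genes had a median of 0.19, at camera adjusted p = 0.00365 (adjusted p = 0.534 with an estimated correlation), lost at adjusted p = 0.258 without DMSO replicate 1. Spliceosome genes had a median of -0.16, at camera adjusted p = 0.0374 (adjusted p = 0.534 with an estimated correlation), lost at adjusted p = 0.159 without DMSO replicate 2 and 0.150 without RG3039 replicate 2.

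Genes of mRNA decapping and decay, the pathway in which DcpS works, did not pass with RG3039. Of 72 tested members, 3 were called higher and 5 lower (3 and 5 adjusted over the list alone). Their median was -0.11 (camera adjusted p = 0.214). Within the list BTG1 (1.01 ± 0.14) and CNOT6 (1.59 ± 0.16), both tied to the CCR4-NOT deadenylase, rose at adjusted p = 0.00320 and 0.000750. Among interferon-stimulated genes GBP2 rose (3.39 ± 0.26) and PARP14 fell (-1.84 ± 0.28), at adjusted p = 0.000372 and 0.00419. That list did not pass (median -0.07, camera adjusted p = 0.605), nor did cancer-testis and germline genes (median 0.24, camera adjusted p = 0.234), of which TDRD9 alone was called (5.17 ± 0.51, adjusted p = 0.000743). The imprinted genes IGF2R (1.01 ± 0.13) and PLAGL1 (-2.77 ± 0.42) and the endothelial and myeloid adhesion gene PECAM1 (1.55 ± 0.20) changed at adjusted p of 0.00432 or less. Median, mean and test direction differed in sign for primary granule and promyelocyte genes (0.10, -0.15 and down), apoptosis regulators (-0.10, 0.14 and up), DNA methylation machinery and decitabine metabolism genes (-0.02, 0.03 and down) and imprinted genes (-0.08, 0.15 and up), none of which passed. With the estimated correlation held fixed, the list calls for mitosis, spliceosome and splicing factor and lysosome did not hold. Of 73 called genes within the naming rule, 36 kept the call without each of the 8 libraries, all called genes named above for this comparison among them. The number of called genes was 637 without DMSO replicate 2, 556 without RG3039 replicate 1 and 496 without RG3039 replicate 2.

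With both drugs together, 4221 of 17534 genes, or 24.1%, were called against DMSO, 1999 higher and 2222 lower. Myeloid maturation markers rose. Of 60 tested markers, 38 were called higher and 3 lower (41 and 5 adjusted over the list alone). Their median was 1.29, at camera adjusted p = 3.33e-12 (adjusted p = 0.100 with an estimated correlation). MMP9 went from 9.07 ± 2.15 in DMSO to 952 ± 16 (mean ± SD, n = 2). Among them were MMP9 (6.58 ± 0.33) and NCF1 (2.58 ± 0.19), at adjusted p of 4.98e-05 or less. NCF1 encodes a subunit of the phagocyte NADPH oxidase and has near-identical pseudogenes. Genes of MYC and ribosome biogenesis fell. Of 41 tested members, 0 were called higher and 35 lower (0 and 38 adjusted over the list alone). Their median was -1.02, at camera adjusted p = 2.37e-20 (adjusted p = 0.100 with an estimated correlation). Examples are NOP16 (-1.69 ± 0.16), MRTO4 (-1.65 ± 0.17), UTP20 (-1.32 ± 0.15) and HSPE1 (-1.70 ± 0.16), at adjusted p of 0.000352 or less. MYC, chosen after its values were seen, fell from 2835 ± 168 to 564 ± 90.2 (-2.34 ± 0.29, adjusted p = 0.000626).

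MYL9, a myosin light chain gene (ENSG00000101335.10, chromosome 20, 36541484 to 36551447 on GRCh38), was at 0.757 and 0 in DMSO, 31.0 and 30.1 with decitabine, 26.9 and 24.7 with RG3039 and 432 and 558 with both. Its change with the combination was 8.54 ± 0.54 (adjusted p = 2.35e-05). The long non-coding RNA AL160408.3 (ENSG00000230628.1, chromosome 1, 234669523 to 234696153) was at 1.51 and 1.51 in DMSO, 167 and 191 with decitabine, 2.69 and 7.16 with RG3039 and 648 and 706 with both (8.08 ± 0.52, adjusted p = 2.47e-05). PPP1R1B reached 933 ± 28.5 (7.60 ± 0.40, adjusted p = 8.61e-06), and IGFBP7 fell to 16.1 ± 4.94 (-7.16 ± 0.34, adjusted p = 4.61e-06). The kinase anchoring protein gene AKAP12 was listed at 0 in both DMSO libraries. It stood at 47.0 and 53.7 with decitabine, 0 and 1.94 with RG3039 and 239 and 273 with both (adjusted p = 0.000202). VARS2, which encodes the mitochondrial valyl-tRNA synthetase, was also listed at 0 in both DMSO libraries, against 548 and 435 with the combination. Cells need this enzyme in general, so a listed 0 is not read here as absence of the transcript.

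The tested cancer-testis and germline genes were higher with the combination than in DMSO, which the filter on the mean favours. Of 37 tested members, 12 were called higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 1.05, at camera adjusted p = 0.000146 (adjusted p = 0.100 with an estimated correlation). The median was 0.92 without the 5 members listed at 0 in a whole group. They included TKTL1 (5.71 ± 0.73), MAEL (4.46 ± 0.42) and TDRD9 (6.13 ± 0.51), at adjusted p of 0.000698 or less. Of 36 p53 targets, 12 were called higher and 2 lower (14 and 4 adjusted over the list alone). Their median was 0.34, at camera adjusted p = 0.00598 (adjusted p = 0.100 with an estimated correlation). Among them SAT1 (1.95 ± 0.17), NINJ1 (1.78 ± 0.17), CDKN1A (2.96 ± 0.36) and BBC3 (1.30 ± 0.17) rose, at adjusted p of 0.000682 or less. Of 53 lysosome genes, 17 were called higher and 2 lower (19 and 2 adjusted over the list alone). Their median was 0.37, at camera adjusted p = 9.37e-05 (adjusted p = 0.135 with an estimated correlation). They included SQSTM1 (1.98 ± 0.17), CTSD (1.73 ± 0.18) and GAA (3.55 ± 0.38), at adjusted p of 0.000289 or less. Of 51 histone genes, 12 were called higher and 1 lower (12 and 1 adjusted over the list alone). Their median was 0.40, at camera adjusted p = 0.000340 (adjusted p = 0.100 with an estimated correlation). Their leading members were H2BC21 (2.72 ± 0.28) and H2AC13 (3.68 ± 0.37), at adjusted p of 0.000240 or less. Of 19 lymphoid, stromal and epithelial markers, 7 were called higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 1.21, which the filter favours, at camera adjusted p = 0.000340 (adjusted p = 0.100 with an estimated correlation). PECAM1 (2.45 ± 0.20) and the intermediate filament gene VIM (1.39 ± 0.16), which myeloid cells also express, were among them, at adjusted p = 8.03e-05 and 0.000354.

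Several lists of genes that most cells express fell with the combination. Of 75 spliceosome and splicing factor genes, 0 were called higher and 25 lower (0 and 31 adjusted over the list alone). Their median was -0.41, at camera adjusted p = 1.51e-08 (adjusted p = 0.100 with an estimated correlation). They included U2AF1 (-1.46 ± 0.18), SRSF2 (-1.15 ± 0.15) and SF3A3 (-0.81 ± 0.13), at adjusted p of 0.00186 or less. Of 34 cholesterol biosynthesis genes, 2 were called higher and 15 lower (2 and 15 adjusted over the list alone). Their median was -0.52, at camera adjusted p = 0.000271 (adjusted p = 0.100 with an estimated correlation). FASN (-1.43 ± 0.13) and SCD (-1.55 ± 0.18) encode fatty acid synthase and stearoyl-CoA desaturase, and DHCR7 (-1.51 ± 0.18) a late enzyme of cholesterol synthesis. These 3 fell at adjusted p of 0.000499 or less. Of 60 DNA replication genes, 5 were called higher and 15 lower (5 and 17 adjusted over the list alone). Their median was -0.20, at camera adjusted p = 0.00609 (adjusted p = 0.163 with an estimated correlation). Of 72 mRNA decapping and decay genes, 4 were called higher and 19 lower (5 and 26 adjusted over the list alone). Their median was -0.36, at camera adjusted p = 0.000340 (adjusted p = 0.283 with an estimated correlation). Of 25 m6A genes, 1 was called higher and 7 lower (2 and 10 adjusted over the list alone). Their median was -0.30, at camera adjusted p = 0.00972 (adjusted p = 0.151 with an estimated correlation). The RNA exosome gene EXOSC5 (-1.24 ± 0.16) and the m6A methyltransferase genes METTL3 (-1.67 ± 0.31) and METTL16 (-1.41 ± 0.25) fell at adjusted p of 0.00484 or less. Of 54 mitosis genes, 13 were called higher and 3 lower (13 and 3 adjusted over the list alone). Their median was 0.22, at camera adjusted p = 0.00772 (adjusted p = 0.458 with an estimated correlation). This call was lost at adjusted p = 0.202 without DMSO replicate 1.

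The other lists did not pass with the combination. Of 49 interferon-stimulated genes, 9 were called higher and 3 lower (10 and 3 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.117). Among them GBP2 (5.59 ± 0.26), IFI6 (2.19 ± 0.35) and IFITM2 (1.56 ± 0.26) rose, at adjusted p of 0.00250 or less. Of 27 antigen presentation genes, 5 were called higher and 7 lower (6 and 8 adjusted over the list alone). Their median was 0.08 (camera adjusted p = 0.910). CD74 fell (-1.35 ± 0.20, adjusted p = 0.00132). Of 29 primary granule and promyelocyte genes, 8 were called higher and 9 lower (10 and 12 adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.815). DEFA1 fell (-2.04 ± 0.16) and RNASE3 rose (2.25 ± 0.18), at adjusted p = 6.94e-05 and 6.94e-05. Of 45 apoptosis regulators, 10 were called higher and 7 lower (11 and 8 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.590). BCL2 fell (-1.47 ± 0.14) and BIRC3 rose (2.95 ± 0.37), at adjusted p = 0.000159 and 0.000616. Of 32 DNA methylation and decitabine metabolism genes, 3 were called higher and 9 lower (3 and 11 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 0.0701). CDA rose to 3492 ± 476 (3.04 ± 0.19, adjusted p = 2.06e-05).

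Of 42 integrated stress response genes tested with the combination, 9 were called higher and 8 lower (9 and 9 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.762). Of 30 imprinted genes, 4 were called higher and 3 lower (5 and 3 adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.479). Of 25 erythroid and megakaryocyte markers, 3 were called higher and 0 lower (3 and 0 adjusted over the list alone). Their median was 0.59 (camera adjusted p = 0.0701). Of 15 mitochondrially encoded genes, 1 was called higher and 3 lower (1 and 3 adjusted over the list alone). Their median was -0.17 (camera adjusted p = 0.131). The counts were 1 and 1 without DMSO replicate 2, 0 and 0 without combination replicate 2, and 0 and 1 without DMSO replicate 1, RG3039 replicate 1, RG3039 replicate 2 or combination replicate 1. Median, mean and test direction differed in sign for antigen presentation genes (0.08, -0.23 and down) and primary granule and promyelocyte genes (-0.09, 0.01 and down). With the estimated correlation held fixed, the list calls for mitosis and mRNA decapping and decay did not hold. Of 102 called genes within the naming rule, 81 kept the call without each of the 8 libraries. At least 2-fold change was reached by 2620 of the called genes, and 72 called genes had a whole group listed at 0. The number called was 2783 without DMSO replicate 2, 2133 without combination replicate 1 and 2391 without combination replicate 2.

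**Figure D2:**
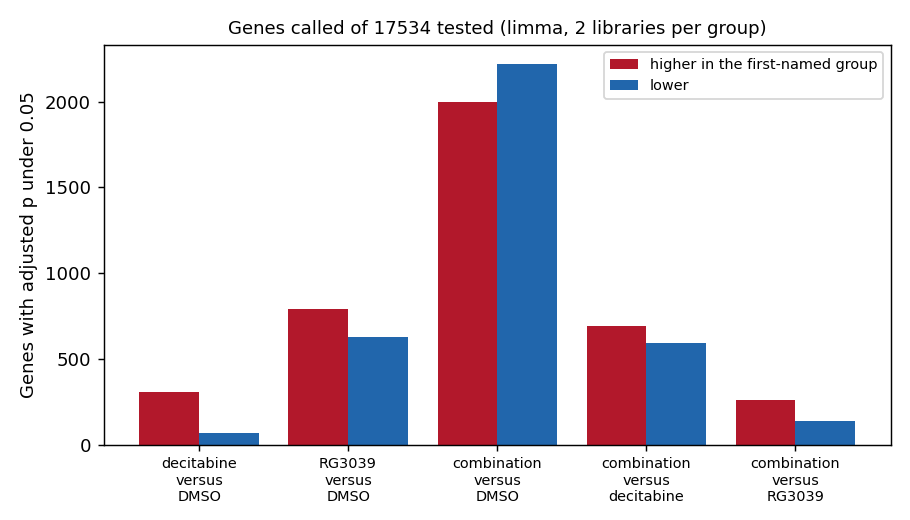
Number of genes with an adjusted p under 0.05 (limma, 2 libraries per group, 17534 genes tested) in each pairwise comparison, with red bars for genes higher and blue bars for genes lower in the first-named group. The combination against DMSO has 1999 and 2222, RG3039 794 and 630, and decitabine 305 and 71.

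**Figure D3:**
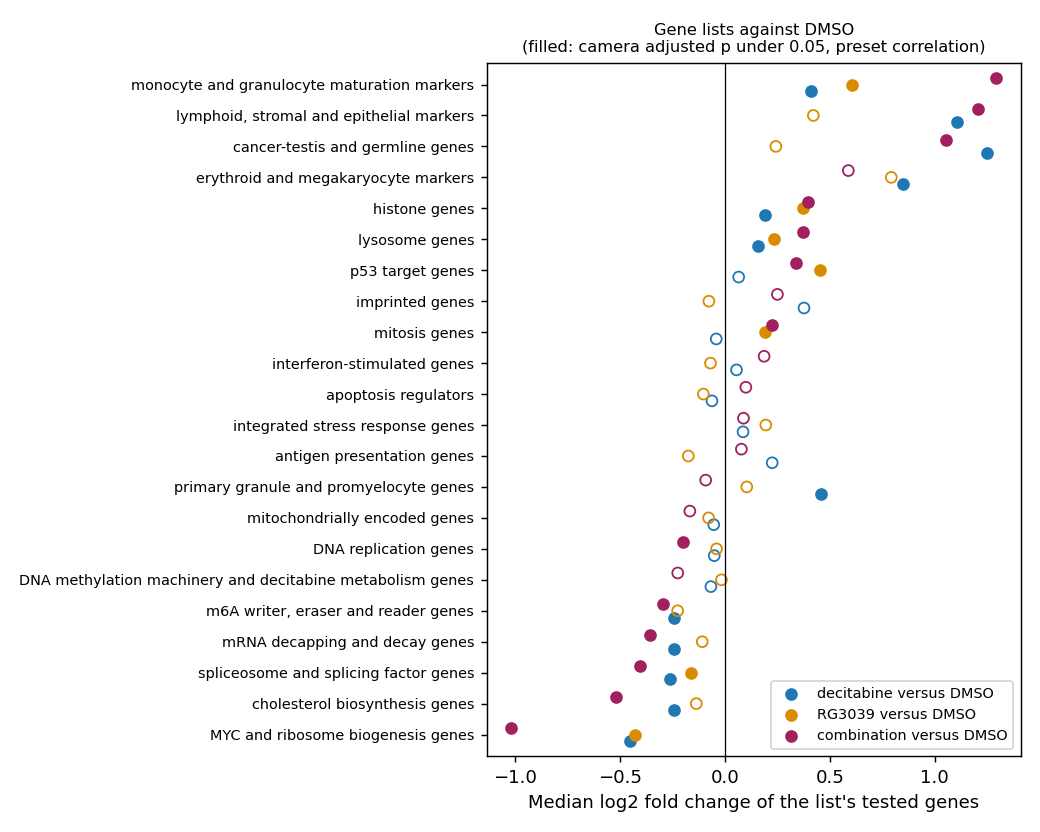
Median log2 fold change of the tested genes of each of the 22 lists against DMSO, with 1 point per treatment and filled points for a camera adjusted p under 0.05 at the preset correlation (no list passed with an estimated correlation). The combination is lowest for MYC and ribosome biogenesis genes (-1.02) and highest for monocyte and granulocyte maturation markers (1.29).

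Adding RG3039 to decitabine lowered IGFBP7 from 1199 ± 364 to 16.1 ± 4.94 (mean ± SD, n = 2), a change of -6.13 ± 0.34 (adjusted p = 0.000191). It raised the long non-coding RNA LINC00877 (ENSG00000241163.8, chromosome 3, 72035300 to 72279503 on GRCh38) from 10.1 ± 9.76 to 517 ± 70.2 (5.89 ± 0.72, adjusted p = 0.00213). Maturation markers rose. Of 60 tested markers, 23 were called higher and 2 lower (35 and 2 adjusted over the list alone). Their median was 0.62, at camera adjusted p = 1.76e-13 (adjusted p = 0.116 with an estimated correlation). They included MMP9 (3.41 ± 0.33) and S100A9 (1.74 ± 0.16), at adjusted p of 0.00103 or less. Primary granule and promyelocyte genes fell as a set. Of 29 tested members, 2 were called higher and 12 lower (3 and 14 adjusted over the list alone). Their median was -0.53, at camera adjusted p = 3.79e-05 (adjusted p = 0.258 with an estimated correlation). CTSG (-2.57 ± 0.21) and PRTN3 (-1.33 ± 0.16), which encode the proteases cathepsin G and proteinase 3, and DEFA1 (-1.32 ± 0.16) fell at adjusted p of 0.00214 or less. Genes of MYC and ribosome biogenesis fell too. Of 41 tested members, 0 were called higher and 16 lower (0 and 32 adjusted over the list alone). Their median was -0.62, at camera adjusted p = 1.14e-15 (adjusted p = 0.179 with an estimated correlation). NOP16 was among them (-1.30 ± 0.16, adjusted p = 0.00249).

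The comparison of the combination with decitabine called 1286 genes, 691 higher and 595 lower in the combination, 818 of them at least 2-fold. Without the mean-variance trend 432 were called. Of 36 p53 targets, 7 were called higher and 0 lower (8 and 0 adjusted over the list alone). Their median was 0.26, at camera adjusted p = 0.00480 (adjusted p = 0.179 with an estimated correlation). They included SAT1 (1.63 ± 0.17), NINJ1 (1.61 ± 0.17) and BBC3 (1.44 ± 0.17), at adjusted p of 0.00171 or less, and BCL2 fell (-1.05 ± 0.14, adjusted p = 0.00320). CDA was at 775 ± 98.1 with decitabine and 3492 ± 476 with both (2.17 ± 0.19, adjusted p = 0.000829). Further genes that rose were GBP2 (3.12 ± 0.26), SQSTM1 (1.53 ± 0.17) and H2BC21 (2.17 ± 0.28), at adjusted p of 0.00297 or less. Lysosome genes had a median of 0.17, at camera adjusted p = 0.000684 (adjusted p = 0.258 with an estimated correlation). Histone genes had a median of 0.32, at camera adjusted p = 0.00374 (adjusted p = 0.225 with an estimated correlation). Mitosis genes had a median of 0.29, at camera adjusted p = 2.66e-06 (adjusted p = 0.269 with an estimated correlation). Cholesterol biosynthesis genes had a median of -0.37, at camera adjusted p = 0.00150 (adjusted p = 0.225 with an estimated correlation). DNA replication genes had a median of -0.19, at camera adjusted p = 0.00744 (adjusted p = 0.258 with an estimated correlation), lost at adjusted p = 0.113 without decitabine replicate 2. Spliceosome genes had a median of -0.10, at camera adjusted p = 0.00374 (adjusted p = 0.314 with an estimated correlation), lost at adjusted p = 0.141 without decitabine replicate 2. With the estimated correlation held fixed, the list calls for primary granule and promyelocyte, mitosis, DNA replication, spliceosome and splicing factor and lysosome did not hold.

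No cancer-testis or germline gene was called between the combination and decitabine. Of 37 tested members, 0 were called higher and 0 lower (0 and 0 adjusted over the list alone). Their median was -0.27 (camera adjusted p = 0.353). TKTL1 gave -2.28 ± 0.73 (adjusted p = 0.0929). COL14A1 was lower (-3.83 ± 0.76, adjusted p = 0.0180), as was PNMA5 (-1.43 ± 0.32, adjusted p = 0.0261). For this comparison these 3 genes were chosen after their values were seen. The call was lost at adjusted p = 0.132 without decitabine replicate 1, 0.113 without decitabine replicate 2, 0.0912 without combination replicate 1 and 0.123 without combination replicate 2 for COL14A1. For PNMA5 it was lost at adjusted p = 0.0882 without decitabine replicate 1, 0.145 without decitabine replicate 2, 0.170 without combination replicate 1 and 0.118 without combination replicate 2. Median, mean and test direction differed in sign for integrated stress response genes (-0.07, -0.03 and up) and imprinted genes (-0.03, 0.01 and down). Of 71 called genes within the naming rule, 21 kept the call without each of the 8 libraries. The number called was 398 without decitabine replicate 1, 576 without decitabine replicate 2, 305 without combination replicate 1 and 308 without combination replicate 2.

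Adding decitabine to RG3039 raised AL160408.3 from 2.69 and 7.16 to 648 and 706 (6.95 ± 0.52, adjusted p = 0.000390). MAGEB2 (ENSG00000099399.6, chromosome X, 30215560 to 30220089 on GRCh38) went from 28.9 ± 8.61 to 300.2 ± 36.1 (mean ± SD, n = 2), a change of 3.36 ± 0.32 (adjusted p = 0.00177). GATA2 rose (1.71 ± 0.17, adjusted p = 0.00204). GP1BB was listed at 0 in both RG3039 libraries and at 1013 and 665 with both drugs. Tested cancer-testis and germline genes rose as a set, which the filter on the mean again favours. Of 37 tested members, 7 were called higher and 0 lower (11 and 0 adjusted over the list alone). Their median was 0.59, at camera adjusted p = 3.19e-05 (adjusted p = 0.0898 with an estimated correlation). The median was 0.24 without the 4 members listed at 0 in a whole group. Of 60 maturation markers, 10 were called higher and 0 lower (27 and 1 adjusted over the list alone). Their median was 0.56, at camera adjusted p = 5.55e-11 (adjusted p = 0.0840 with an estimated correlation). Of 41 MYC and ribosome biogenesis genes, 0 were called higher and 8 lower (0 and 32 adjusted over the list alone). Their median was -0.63, at camera adjusted p = 2.49e-22 (adjusted p = 0.0840 with an estimated correlation).

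The comparison of the combination with RG3039 called 399 genes, 261 higher and 138 lower, 281 of them at least 2-fold. With no filter on low values 213 were called, without the mean-variance trend 147 and with a replicate block 688. Of 49 interferon-stimulated genes, 3 were called higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 0.33, at camera adjusted p = 0.000187 (adjusted p = 0.107 with an estimated correlation). Lysosome genes had a median of 0.22, at camera adjusted p = 0.000306 (adjusted p = 0.153 with an estimated correlation). Markers of lymphoid, stromal and epithelial cells had a median of 1.02, at camera adjusted p = 2.28e-05 (adjusted p = 0.0840 with an estimated correlation). Spliceosome genes had a median of -0.27, at camera adjusted p = 6.88e-11 (adjusted p = 0.0898 with an estimated correlation). Cholesterol biosynthesis genes had a median of -0.37, at camera adjusted p = 2.01e-06 (adjusted p = 0.0840 with an estimated correlation). DNA replication genes had a median of -0.21, at camera adjusted p = 3.19e-05 (adjusted p = 0.0914 with an estimated correlation). Genes of mRNA decapping and decay had a median of -0.22, at camera adjusted p = 0.000107 (adjusted p = 0.225 with an estimated correlation). The m6A genes had a median of -0.20, at camera adjusted p = 0.0140 (adjusted p = 0.153 with an estimated correlation). DNA methylation machinery and decitabine metabolism genes had a median of -0.25, at camera adjusted p = 0.0179 (adjusted p = 0.107 with an estimated correlation), lost at adjusted p = 0.0903 without RG3039 replicate 2 and 0.0707 without combination replicate 1. With the estimated correlation held fixed, the list call for mRNA decapping and decay did not hold. Genes listed as p53 targets did not pass (median -0.05, camera adjusted p = 0.713). Median, mean and test direction differed in sign for p53 target genes (-0.05, 0.11 and up), apoptosis regulators (0.01, -0.01 and down) and erythroid and megakaryocyte markers (-0.11, 0.18 and up). Of 51 called genes within the naming rule, 5 kept the call without each of the 8 libraries (GP1BB, AL160408.3, MAGEB2 and GATA2 among them). The number called was 255 without decitabine replicate 1, 213 without decitabine replicate 2, 59 without RG3039 replicate 1, 177 without RG3039 replicate 2, 21 without combination replicate 1 and 34 without combination replicate 2.

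The interaction asks whether the response to both drugs differs from the sum of the single responses on the log2 scale. No gene passed: 0 of 17534 were called by limma, 1014 had an unadjusted p under 0.05, and no other tool was run. Simulated changes of 2-fold, 4-fold and 8-fold in this contrast were recovered for 7 of 67, 43 of 67 and 52 of 66 genes, so departures of 2-fold were mostly not detectable. Among the gene lists, primary granule and promyelocyte genes ended below the sum of the single responses. Of 29 tested members, 0 were called higher and 0 lower (0 and 4 adjusted over the list alone). Their median was -0.52, at camera adjusted p = 1.58e-08 (adjusted p = 0.478 with an estimated correlation). A further 5 lists passed with negative medians, each losing the call without some library. Cancer-testis and germline genes had a median of -0.69, at camera adjusted p = 0.00846 (adjusted p = 0.478 with an estimated correlation), lost at adjusted p = 0.170 without DMSO replicate 2, 0.0532 without decitabine replicate 2 and 0.139 without combination replicate 2. DNA replication genes had a median of -0.17, at camera adjusted p = 0.00762 (adjusted p = 0.478 with an estimated correlation), lost at adjusted p = 0.0802 without DMSO replicate 1 and 0.101 without decitabine replicate 2. Cholesterol biosynthesis genes had a median of -0.18, at camera adjusted p = 0.0311 (adjusted p = 0.478 with an estimated correlation), lost at adjusted p = 0.177 without DMSO replicate 2, 0.193 without decitabine replicate 2, 0.162 without RG3039 replicate 2 and 0.139 without combination replicate 2. Erythroid and megakaryocyte markers had a median of -0.73, at camera adjusted p = 0.00762 (adjusted p = 0.672 with an estimated correlation), lost at adjusted p = 0.818 without DMSO replicate 2, 0.0860 without decitabine replicate 2 and 0.456 without combination replicate 2. MYC and ribosome biogenesis genes had a median of -0.16, at camera adjusted p = 0.00762 (adjusted p = 0.592 with an estimated correlation), lost at adjusted p = 0.310 without DMSO replicate 1 and 0.225 without decitabine replicate 2. Median, mean and test direction differed in sign for apoptosis regulators (-0.08, -0.04 and up), mRNA decapping and decay genes (0.02, -0.05 and down), m6A writer, eraser and reader genes (0.07, -0.04 and up), imprinted genes (0.07, -0.15 and up), lymphoid, stromal and epithelial markers (-0.01, -0.07 and up) and mitochondrially encoded genes (0.01, -0.11 and down), none of which passed. The number of genes called was 1 without DMSO replicate 1, 2 without DMSO replicate 2, 2 without RG3039 replicate 1 and 1 without combination replicate 2. The number of lists called was 3 without DMSO replicate 2, 1 without decitabine replicate 2 and 3 without combination replicate 2.

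The responses shared many called genes. Decitabine and RG3039 against DMSO had 145 genes called higher in both and 35 lower in both, against 13.8 and 2.55 expected of independent lists, and 4 called in opposite directions. Decitabine and the combination had 289 genes called higher in both and 62 lower in both, against 34.8 and 9 expected of independent lists, and 1 called in opposite directions. RG3039 and the combination had 733 genes called higher in both and 527 lower in both, against 90.5 and 79.8 expected of independent lists, and 2 called in opposite directions. The 3 comparisons use the same 2 DMSO libraries and the same estimate of the spread per gene. Fold changes correlated across genes, which are not independent replicates, at 0.475, 0.676 and 0.712, and at 0.502, 0.5 and 0.503 in 20 simulations of unchanged groups with shared controls. With a DMSO library of its own for each comparison, chosen after the data were seen, no control is shared. With DMSO replicate 1 for the first-named treatment and replicate 2 for the other, decitabine and RG3039 had 57 genes called higher in both and 1 lower in both (5.26 and 0.256 expected). Decitabine and the combination had 124 and 2 (12.96 and 0.903 expected), and RG3039 and the combination 370 and 156 (41.3 and 20.47 expected). Called in opposite directions were 1, 0 and 2 genes. In the other assignment the counts were 87 and 6 (8.32 and 1.84 expected), 234 and 88 (28.75 and 11.6 expected) and 465 and 316 (57.9 and 36.6 expected). Here 6, 10 and 4 genes were called in opposite directions, so for decitabine and RG3039 as many genes were opposite as were lower in both. Fold changes then correlated at 0.181 and 0.140 in the 2 assignments for decitabine and RG3039, 0.415 and 0.356 for decitabine and the combination and 0.437 and 0.419 for RG3039 and the combination.

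In all 3 comparisons against DMSO, 181 genes were called. A further 171 were called with decitabine and the combination only, 1081 with RG3039 and the combination only, and 2788 with the combination only. Of those 2788, 77 were also called against both single drugs. The overlap of decitabine and RG3039 was 282 without DMSO replicate 1, 70 without DMSO replicate 2, 50 without decitabine replicate 1, 38 without decitabine replicate 2, 73 without RG3039 replicate 1, 72 without RG3039 replicate 2, 71 without combination replicate 1 and 72 without combination replicate 2. That of decitabine and the combination was 140 without DMSO replicate 2, 81 without decitabine replicate 1, 68 without decitabine replicate 2, 151 without combination replicate 1 and 144 without combination replicate 2. That of RG3039 and the combination was 594 without DMSO replicate 2, 521 without RG3039 replicate 1, 435 without RG3039 replicate 2, 803 without combination replicate 1 and 772 without combination replicate 2.

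**Figure D4:**
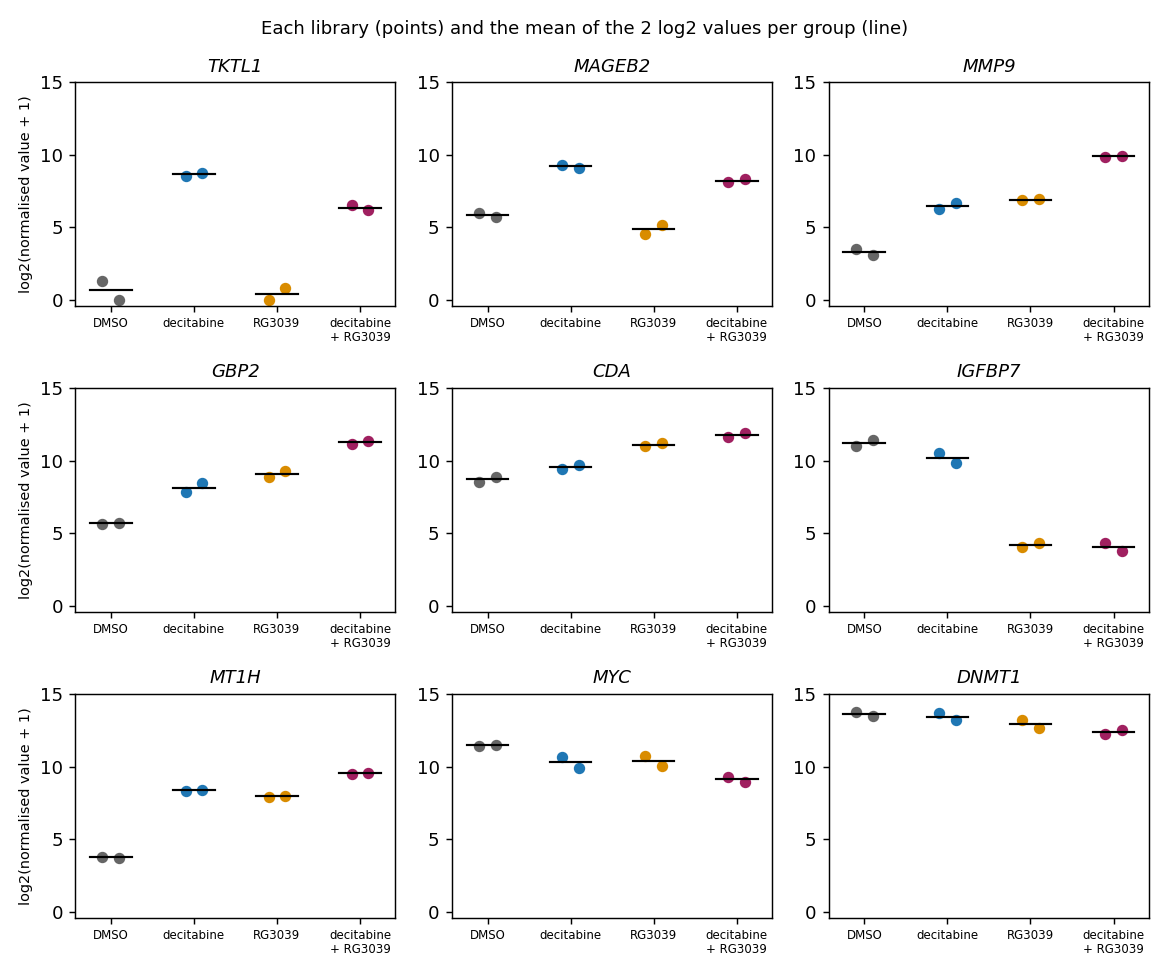
log2(normalised value + 1) of 9 genes in each library (points) and the mean of the 2 log2 values per group (line), with the 4 treatments on the horizontal axis. TKTL1 and MAGEB2 are highest with decitabine, MMP9, GBP2 and CDA highest and MYC and DNMT1 lowest with the combination, IGFBP7 is low in both groups that received RG3039, and MT1H is higher with each treatment than with DMSO (MYC and MT1H were chosen after their values were seen).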

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

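The test with the correlation held fixed was chosen only after the result was seen; the other tests in this part were fixed before theirs.

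Of the 22 gene lists, 6 gave a response to both drugs that differed from the sum of the single responses by a test of the difference itself (the interaction, camera at its preset correlation), although no single gene passed. The median interactions, in log2 units, were -0.69 for cancer-testis and germline genes, -0.52 for primary granule and promyelocyte genes, -0.17 for DNA replication genes, -0.18 for cholesterol biosynthesis genes, -0.73 for erythroid and megakaryocyte markers and -0.16 for MYC and ribosome biogenesis genes. The adjusted p-values were 0.00846, 1.58e-08, 0.00762, 0.0311, 0.00762 and 0.00762 in that order, and 0.478, 0.478, 0.478, 0.478, 0.672 and 0.592 with an estimated correlation. For DNA replication, cholesterol biosynthesis and MYC and ribosome biogenesis genes, whose medians fell against DMSO, a negative value is a larger fall than the sum. All but primary granule and promyelocyte genes lost the call without at least 1 library: without DMSO replicate 2 the adjusted p was 0.170 for cancer-testis genes, 0.177 for cholesterol biosynthesis and 0.818 for erythroid and megakaryocyte markers, and without DMSO replicate 1 it was 0.0802 for DNA replication and 0.310 for MYC and ribosome biogenesis. Without decitabine replicate 2 the 5 lists gave 0.0532, 0.193, 0.0860, 0.101 and 0.225 in this order. Without combination replicate 2 cancer-testis genes gave 0.139, cholesterol biosynthesis 0.139 and the erythroid and megakaryocyte markers 0.456, and without RG3039 replicate 2 cholesterol biosynthesis gave 0.162.

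The pattern weighed is that of primary granule and promyelocyte genes, which rose with decitabine (median 0.46) and had a median of -0.09 with the combination. A single library is argued against: over 8 fits, each without 1 library, the largest adjusted p was 0.000130 and the median interaction ran from -0.56 to -0.43. Reads shared between the near-identical defensin genes are also argued against, since without these genes the median over the other 26 was -0.53 (adjusted p = 1.77e-09). Genes of the list varying together between libraries may account for the call: with the estimated correlation held fixed the adjusted p was 0.0596, and 0.478 in camera's own version. That stays open, as does the biological explanation that the drugs act on the same genes, which was not tested beyond the interaction itself.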

How the results depend on the processing

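Tests with the correlation held fixed, with genes above 0 in all 8 libraries, with genes of 1 transcript, with TMM for the gene lists and with separate DMSO libraries were chosen after seeing the data; the other alternatives were fixed before. The replicates are duplicate wells, so p-values measure only the spread between these wells. Alternatives with edgeR and DESeq2 on recovered reads were not run, since reads were recovered for part of the genes only.

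Counts of called genes, overlaps and lists stayed within 1.5 times the reported ones under TMM scaling, quantile normalization and a mean of at least 50, and counts of genes and overlaps did so with pseudocounts of 0.5 and 5 and with robust estimates. Genes above 0 in all 8 libraries gave gene counts within 1.5 times. No direction reversed: of the settings applied to each named and called gene, 5510 kept the call and 1016 lost it, and for the called lists 718 kept it and 122 lost it.

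Other settings lowered counts. With no filter on low values, more genes were tested, and decitabine against DMSO had 225 calls, the combination against RG3039 213, the overlap of decitabine with RG3039 97 and with the combination 205. Without the mean-variance trend, calls were 210 for decitabine, 718 for RG3039, 432 for the combination against decitabine and 147 against RG3039, and the overlaps were 85 (decitabine and RG3039), 197 (decitabine and combination) and 644 (RG3039 and combination); the cause was not tested. With only the groups compared, which leaves fewer samples, decitabine had 105 calls and RG3039 481, and the overlaps were 26, 90 and 451. Among the 3341 tested genes with 1 transcript, calls were 53 for decitabine, 190 for RG3039, 412 for the combination, 143 for the combination against decitabine and 45 against RG3039. For the combination against DMSO this is 12.3% of these genes, against 24.1% of all tested, so fewer genes alone do not account for it; 2574 of the 3341 are not listed as protein-coding. With a DMSO library of its own for each comparison, which leaves fewer samples, the overlaps were 58 and 93 in the 2 assignments (decitabine and RG3039), 126 and 322 (decitabine and combination) and 526 and 781 (RG3039 and combination). A threshold of 2-fold, stricter by construction, left 2620 calls for the combination against DMSO and 818 against decitabine.

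With an estimated correlation, in camera's own version, 0 lists were called in each of the 6 contrasts. With that correlation held fixed, 7 lists were called for decitabine, 4 for RG3039, 5 for the combination against decitabine and 0 for the interaction, while the combination against DMSO had 12 and against RG3039 11.

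Whether replicates share a batch by number is not given in the labels, and differences between replicates 1 and 2 correlated across genes at 0.161 between DMSO and the combination, 0.117 between DMSO and RG3039, 0.103 between RG3039 and the combination and -0.0767 to 0.0513 in the other pairs of groups. A replicate block gave 525, 1690, 4619, 1678, 688 and 0 calls in the 6 contrasts; the cause was not tested.

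Leaving out each library in turn, which leaves fewer samples and takes the lone one to vary like the other groups, gave 79 to 495 calls for decitabine, 496 to 1263 for RG3039, 2133 to 4075 for the combination, 305 to 1391 for the combination against decitabine, 21 to 454 against RG3039 and 0 to 2 for the interaction. The overlaps ran from 38 to 282 (decitabine and RG3039), 68 to 460 (decitabine and combination) and 435 to 1137 (RG3039 and combination). Lists called ran from 10 to 12, 6 to 9, 13 to 14, 8 to 10, 11 to 14 and 1 to 9 in the order of the contrasts. The lowest number of calls came without decitabine replicate 2 for decitabine (79), without RG3039 replicate 2 for RG3039 (496), without combination replicate 1 for the combination against DMSO (2133), decitabine (305) and RG3039 (21), and without decitabine replicate 2 for the lists of the interaction (1).

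With 2 libraries per group, 10.4% of simulated 2-fold changes were recovered in the interaction. Estimated depths were 20700000 to 40900000 reads, and the effect of depth on detection was not tested.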

Other observations

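All tests in this part were chosen after the data were seen, except that on protein-coding genes with 1 transcript, which was fixed before its result.

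Metallothionein genes rose with every treatment. Of 8 tested MT1 and MT2 genes, 5 were called higher with decitabine, 7 with RG3039 and 7 with the combination against DMSO (adjusted p = 2.16e-05, 1.87e-06 and 0.000311 over 1566 tests of symbol families, which take genes as independent). By chance 0.139, 0.362 and 0.912 were expected. MT1H gave 4.64 ± 0.25, 4.21 ± 0.25 and 5.78 ± 0.25 on the log2 scale, and MT2A 1.63 ± 0.17, 1.75 ± 0.17 and 2.38 ± 0.17, each kept without any 1 of the 8 libraries. The count for decitabine was 3 without decitabine replicate 1 and 3 without decitabine replicate 2. MT1 genes are near-identical, so single members are uncertain.

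With the combination, mitochondrial ribosomal protein genes fell: 31 of 52 tested genes with symbols beginning MRPL and 18 of 33 beginning MRPS were called lower (adjusted p = 2.57e-12 and 4.07e-06), as were 8 of 9 genes of the outer membrane import complex beginning TOMM (adjusted p = 0.000118). Of 11 chemokine genes beginning CCL, 10 were called higher (adjusted p = 1.87e-06). Without combination replicate 1 these counts were 14, 9, 4 and 5, without combination replicate 2 TOMM and MRPL had 5 and 18, and without DMSO replicate 2 TOMM had 5.

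Among genes called higher with decitabine, 26 of 558 on chromosome X stood against 9.71 expected (adjusted p = 0.000811 over 150 tests). The number was 11 without DMSO replicate 2, 6 without decitabine replicate 1, 6 without decitabine replicate 2, 13 without combination replicate 1 and 11 without combination replicate 2. Genes at 3 or less in both DMSO libraries and at 20 or more in both treated ones numbered 53 with decitabine, 12 of them on X, 19 with RG3039, 1 on X, and 106 with the combination, 11 on X. The reverse held for 2, 12 and 24 genes. Of the 53 genes, 37 were among the 106, and of the 19, 14 were.

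Of 35 tested genes on the mitochondrial chromosome, 13 were called higher with the combination and 8 with RG3039 (3.99 and 1.585 expected, adjusted p = 0.00453 and 0.00507 over the same tests). These were nearly all mitochondrial tRNA genes: of 20, 12 were called higher with the combination (median 1.55) and 8 with RG3039 (median 0.89). Of the 13 protein-coding ones, 0 were called higher and 3 lower with the combination (median -0.30). The 3 fell to 0 without combination replicate 2, and to 1 without DMSO replicate 1, DMSO replicate 2, RG3039 replicate 1, RG3039 replicate 2 or combination replicate 1. The tRNA count for the combination was 11 to 13 without each library and 12 under TMM and quantile scaling. For RG3039 it was 7 under TMM and 8 under quantile scaling, 4 without DMSO replicate 2, 3 without RG3039 replicate 1 and 2 without RG3039 replicate 2. What tags assigned to tRNA genes measure in polyadenylated RNA was not tested.

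The effect of a drug with and without the other can be compared with no library in common. Of the 1424 genes called with RG3039 against DMSO, 1381 had the same sign in the combination against decitabine, and 724 were called there in the same direction (52.7 expected) and 1 in the opposite one. Of the 376 genes called with decitabine, 361 had the same sign in the combination against RG3039, with 177 called in the same direction (5.10 expected) and 0 in the opposite one. Slopes through the called genes were 0.666 for RG3039 and 0.731 for decitabine, and choosing genes by the first of the compared effects lowers them. Across all 17534 genes, which are not independent replicates, the effects correlated at 0.497 and 0.443.

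TKTL1, COL14A1 and PNMA5, raised by decitabine, had lower estimates in the combination than with decitabine alone, which raised the hypothesis that RG3039 weakens the response to decitabine; the pattern was narrowed to these 3 genes after the result. If so, genes that rise with decitabine should have a negative interaction in libraries not used to choose them. Genes were chosen without 1 decitabine and 1 DMSO library, and the interaction was measured with those 2. In the 4 choices its median lay between -0.45 (bootstrap 95% interval -0.83 to -0.22, 42 genes, 29 below 0) and -0.90 (-1.35 to -0.74, 21 genes, 19 below 0). The intervals take genes as independent, and the RG3039 and combination libraries are the same in each choice. Of the 305 genes called higher with decitabine, 205 were higher and 100 lower in the combination than with decitabine, 85 and 9 of them called. Their median interaction was -0.57, measured in the libraries that chose them, which lowers it. The response of these genes was thus less than additive on the log2 scale, as the hypothesis needs. With RG3039 alone 145 of the 305 were called higher too, so a limit on how far both drugs together raise a gene was not told from a weaker effect of decitabine, and the cause in the 3 genes stays open.

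The authors' values carry a correction that leaves genes with several transcripts off whole reads, and such a correction could raise the number of calls with the combination, where 24.1% of tested genes passed. It would make genes with 1 transcript, which show whole reads, pass far less often than genes with 5 or more matched on mean value. The ratio of the shares was 1.262 (bootstrap 95% interval 1.13 to 1.41), 30.6% of 767 genes against 24.3% of 9428, which argues against it as the whole cause. Over the 3341 genes with 1 transcript of any type the share was lower, 14.6% (12.3% when fitted alone), against 27.4% of 10060 genes with 5 or more. Of these 3341, the 2574 not listed as protein-coding had 9.83% called. Matched on mean value the share of genes with 5 or more was 17.01%, a ratio of 0.859 (0.775 to 0.950), so a smaller contribution of such a step stays open.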
